A study of Homo sapiens with 3 samples.

How the data were processed

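RNA from 3 IMR-90 cultures, 1 per siRNA, was profiled on 1-colour Affymetrix arrays, per the labels' protocols. The cells were grown in DMEM-F12 medium with 10% serum and transfected for 24 h with RNAiMAX, and biotin-labelled cRNA was made from 250 ng of total RNA. The deposited values are intensity values, 1 linear signal per probe set, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version and its settings are not given in the sources used here. MAS5 scales each array to a common level, and in the deposited table the mean without the extreme 2% of values was 497 on all 3 arrays, so no further scaling was applied. Such scaling assumes similar total expression on each array and would hide a shift of all genes. Detection calls were not used here. Low signals may therefore be background, and the highest signals, up to 36667, may be compressed.

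Probe sets were named through a table of GEO's platform annotation, updated by gene number to the symbols of the RefSeq annotation of GRCh38.p14 (41037 of 41091 matched). Of 54613 probe sets, 41091 had 1 gene symbol, 1801 had several and were left out, and 11721 were not listed and stay unnamed. No coordinates are given. Values under a floor of 11.7, the 25th percentile of all values, were set to it before taking log2. Each of 19775 genes was represented by its probe set with the highest mean log2 value, and 8143 genes had over 1 probe set. Genes were kept if that mean reached the median over all probe sets (5.39 on the log2 scale, a signal of 42.0), which left 12307. A fold change against an array at the floor is a lower bound on the ratio of deposited signals, and its size depends on the floor.

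The 2 SETD8 siRNAs are separate treatments of 1 target and were each set against the control siRNA. With 1 array per siRNA there is no replicate check, the number of arrays limits the precision, and no p-value was computed. Genes were counted by a fixed size, at least 2-fold in the same direction with both siRNAs, and the same count was made with each SETD8 siRNA array in the place of the control. Unchanged arrays sharing a control were simulated 100 times, with noise by signal level from the difference between the SETD8 siRNA arrays divided by the square root of 2. Of 26 gene lists, the leukocyte markers had no gene above the filter, and the median of each other list was placed among 10000 random lists of the same size drawn from 20 bins of mean signal. Tested on simulated data over 12307 genes, the 2-fold rule recovered 17 of 50 genes changed 2-fold (34%), 47 of 50 changed 4-fold (94%), 50 of 50 changed 8-fold and 48 of 50 changed 16-fold (96%), and it called 657 of 12107 unchanged genes (5.43%). Genes changed by about 2-fold are thus often missed, and a single call of that size is weak.

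The lists, the comparisons, the main alternatives and the rule for named genes were fixed before the data were examined, whereas the tests of explanations in the closing section were chosen after the results were seen. The rule named KMT5A, the 12 genes with the largest shared change in each direction, up to 4 members per list with the largest change in the same direction, 20 fixed genes, of which 1 is not analysed here, and the 3 genes most different between the siRNAs in each direction. It gave 135 genes. Genes named outside it were chosen after their values were seen: ESPL1, NRG1, STC1, PLAT, IFI6, ISG15, SPRY2, SLC7A11 and KRT18 in the comparisons, and H3C8, TAGLN, CNN1, LMOD1, SLBP, PTGS2, POSTN, ANKRD1, ID1, ID3, COL10A1, NUP155, NUP107, EXOSC8 and HAUS6 in the closing section. Cell type marker lists covered fibroblasts, epithelium, endothelium and leukocytes.

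Alternatives were median scaling, quantile normalization, a pseudocount of 16 in place of the floor, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, shared probe sets (suffixes _s_at, _x_at and _a_at) left out, and thresholds of 1.5-fold and 3-fold. The narrower simulation noise, the removal of the proliferation lists, and a choice of probe set and signal cut from the control array alone for the histone list were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.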

Results

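Gene expression was measured in IMR-90 cells, which are human fetal lung fibroblasts, 24 h after transfection of 1 of 3 siRNAs. The control siRNA was labelled GL3, and the other 2 siRNAs, here SETD8 siRNA 1 and SETD8 siRNA 2, were directed against SETD8. SETD8, also called PR-Set7 and listed under its current symbol KMT5A, is the enzyme that adds the single methyl group to lysine 20 of histone H4. Each siRNA was represented by 1 array, so the data hold 3 arrays, no value has a replicate error, and no p-value is given. Each array reported 54613 probe sets as linear signal. The median signal was 46.2 on the control array, 45.3 with SETD8 siRNA 1 and 44.9 with SETD8 siRNA 2, and the mean without the extreme 2% of values at either end was 497 on each. After a filter on low signal, 12307 genes were compared. The question put by the design was which genes differ in expression when SETD8 is knocked down, with a pair of siRNAs against the same target.

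In place of a replicate error, the absolute log2 difference between the 2 SETD8 siRNA arrays served as a yardstick for single genes. Its 95th percentile was 2.21 in the lowest quartile of signal (42.0 to 184), 1.72 in the second quartile, 1.25 in the third and 1.14 in the highest quartile (from 2103 upward). This spread holds array noise together with any real difference between the siRNAs.

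KMT5A signal was lower with both SETD8 siRNAs on all 4 of its probe sets. On the brightest, the signal was 938.9 with the control siRNA, 431.4 with SETD8 siRNA 1 (45.9% of control) and 584.1 with SETD8 siRNA 2 (62.2% of control). The other probe sets lay between 68.6% and 74.7% of control with SETD8 siRNA 1 and between 73.5% and 86.3% with SETD8 siRNA 2. Averaged over the probe sets, the log2 fold change was -0.64 ± 0.32 (SD over 4 probe sets) with SETD8 siRNA 1 and -0.39 ± 0.23 (SD over 4 probe sets) with SETD8 siRNA 2. The direction of the change therefore matched the labels of both arrays. Its size was under the yardstick of 1.72 for genes of this signal, and 8.90% of the genes in the same signal quartile had a mean change as low or lower. With shared probe sets left out, the brighter of the remaining 2 gave -0.48 and -0.44 in place of -1.12 and -0.68, and the other gave -0.42 and -0.21.

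**Figure D1:**
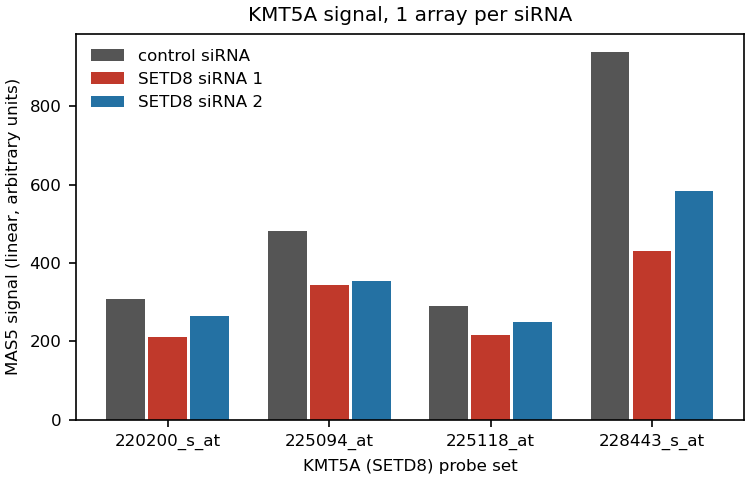
MAS5 signal (linear, arbitrary units) of the 4 KMT5A probe sets on the 3 arrays, 1 bar per array with no error bars because each siRNA had 1 array. Both SETD8 siRNA bars lie under the control bar for every probe set, most clearly for the brightest one (938.9 against 431.4 and 584.1).

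Among the 12 genes with the largest shared decrease were SPC25, a kinetochore subunit, with a signal of 1406.7 in the control, 108.6 with SETD8 siRNA 1 and 117.2 with SETD8 siRNA 2, and the checkpoint kinases BUB1 (log2 fold changes of -3.11 and -3.07, for siRNA 1 and siRNA 2 in that order here and in all pairs that follow) and BUB1B (-3.64 and -3.28). The others were the mitotic kinesin KIFC1 (-3.55 and -4.77), the centromere protein CENPF (-3.42 and -3.28), the spindle proteins DLGAP5 (-3.27 and -3.47) and ASPM (-3.17 and -3.11), the centrosomal kinase NEK2 (-3.21 and -3.30), the condensin subunit NCAPH (-3.13 and -3.17), DEPDC1B (-3.05 and -3.19), the HMG-box factor TOX (-3.82 and -3.39) and the nuclear lamina protein LMNB1 (-3.21 and -3.34). All 12 exceeded the yardstick for their signal with both siRNAs. With probe sets averaged TOX had -2.34 and -2.72 and CENPF -2.78 and -2.85. Without shared probe sets ASPM had -4.77 and -4.09, and with a pseudocount of 16 KIFC1 had -4.08 with SETD8 siRNA 2.

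The 12 genes with the largest shared increase came from several classes. EHF, an ETS-family transcription factor of epithelia, had a signal of 13.9 in the control, 4156.5 with SETD8 siRNA 1 and 596.9 with SETD8 siRNA 2. Its control signal lay next to the floor of 11.7, so no exact fold is given. With the pseudocount its log2 fold changes were 7.12 and 4.36. MX1, an interferon-induced GTPase, was higher by 4.09 and 3.10 on the log2 scale, ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 3.28 and 2.82 (2.55 and 2.37 with probe sets averaged), CBLN2 by 4.23 and 3.69, and COXFA4L3 by 4.80 and 3.03. SPRY4-IT1, a transcript from an intron of SPRY4, was higher by 3.82 and 3.73, and DKK2, a secreted modulator of Wnt signalling, by 3.84 and 2.96. The control signals of MX1 (24.5), CBLN2 (18.6) and SPRY4-IT1 (24.0) were low too, and with the pseudocount the values were 3.42 and 2.48, 3.40 and 2.89, and 3.15 and 3.06. When the probe sets of a gene were averaged, SPRY4-IT1 had 1.85 and 0.97 and DKK2 had 1.11 and 0.94, under 2-fold with SETD8 siRNA 2. The control signal of the remaining genes lay at the floor, so their fold changes are lower bounds: at least 10.8-fold and 9.03-fold for MRGPRX3, 7.83-fold and 8.56-fold for the histone gene H2BC11, 8.39-fold and 7.40-fold for EPOP, 7.20-fold and 7.76-fold for LINC02593, and 31.8-fold and 6.46-fold for THBD, the endothelial thrombin receptor thrombomodulin. These bounds hold for the floor used. With the pseudocount, the log2 values were smaller: 2.35 and 2.46 for H2BC11 and 2.16 and 2.00 for EPOP. LINC02593 had 2.14 and 2.23, and THBD 4.08 and 2.

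Over all genes, 185 were at least 2-fold higher and 398 at least 2-fold lower with both SETD8 siRNAs. SETD8 siRNA 1 alone gave 675 higher and 954 lower genes, and SETD8 siRNA 2 gave 549 and 818. Independent lists of those sizes would share 30.1 higher and 63.4 lower genes. The changes of the 2 siRNAs correlated across genes with a Pearson r of 0.449 and a Spearman rho of 0.414 (genes are not independent replicates), and 65.0% of genes had the same sign. Because both comparisons use the same control array, unchanged arrays were simulated with noise taken from the difference between the SETD8 siRNA arrays. They gave a Pearson r of 0.501 ± 0.0137 (SD over 100 simulations), 346 ± 20.2 higher and 343 ± 17.1 lower genes, and a covariance of 0.327 ± 0.0146 against 0.259 observed. With noise scaled to the interquartile range of that difference, an alternative chosen after seeing the data, the simulated counts were 95.4 and 94.8 and the covariance 0.139. The correlation therefore gives no measure of a shared effect, and under the wider noise the count of higher genes lay below the simulated one and that of lower genes above it. With an SETD8 siRNA array in the place of the control, the count of genes apart from both other arrays was 724 for SETD8 siRNA 1 and 480 for SETD8 siRNA 2, against 583 for the control array. A stricter rule, beyond the yardstick with both siRNAs, left 67 higher and 187 lower genes.

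**Figure D2:**
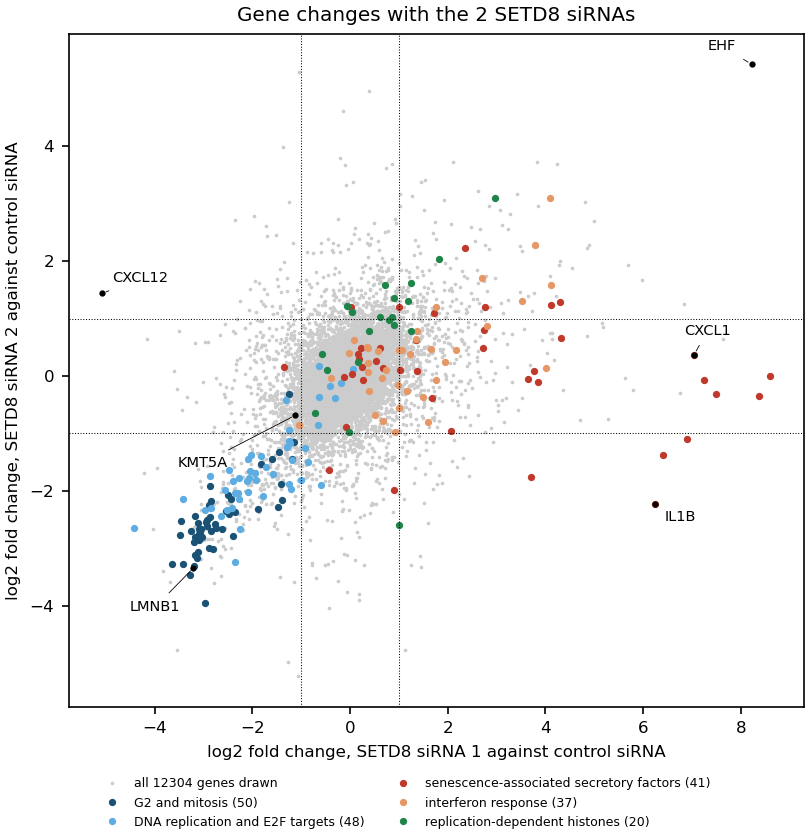
Log2 fold change of each gene against the control siRNA with SETD8 siRNA 1 (horizontal axis) and SETD8 siRNA 2 (vertical axis), 1 point per gene drawn, with 5 gene lists in colour, 6 genes labelled and dotted lines at 2-fold. The G2 and mitosis genes lie together at the lower left (medians of -2.89 and -2.60), whereas the secretory factors spread along the axis of SETD8 siRNA 1 (medians of 1.71 and 0.10).

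Of the 50 G2 and mitosis genes, 49 were at least 2-fold lower with both SETD8 siRNAs and none was higher. The exception was ESPL1, the separase, at -1.25 and -0.32. The median log2 fold change of the list was -2.89 (SD over members 0.68) with SETD8 siRNA 1 and -2.60 (SD 0.64) with SETD8 siRNA 2, or 7.43-fold and 6.06-fold lower, where random lists matched on signal gave medians between -0.20 and 0.12 and between -0.18 and 0.11 (middle 95% of 10000 lists). Examples are the kinesin KIF20A (-2.98 and -3.96), the mitotic kinase CDK1 (-2.88 and -1.92, or -2.50 and -2.39 with probe sets averaged), the proliferation marker MKI67 (-2.51 and -2.07) and cyclin A2, CCNA2, whose signal was 3697.0 in the control, 722.9 with SETD8 siRNA 1 and 716.4 with SETD8 siRNA 2. In all, 47 of the 50 exceeded the yardstick with both siRNAs. No gene of this list had either SETD8 siRNA array as the one standing 2-fold apart from both others.

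DNA replication genes and E2F targets were lower as well, 36 of 48 at least 2-fold with both siRNAs and none higher. The list medians were -1.94 (SD over members 0.91) and -1.76 (SD 0.75), against random ranges of -0.21 to 0.13 and -0.19 to 0.12. The origin licensing factor CDT1 had -4.42 and -2.65 (-2.43 and -1.70 with probe sets averaged), the helicase subunit CDC45 -2.36 and -3.23, DTL -3.41 and -2.15, and MCM10 -2.97 and -2.33. The transcription factor E2F1 had -0.63 and -0.36, the latter being -1.15 without shared probe sets. Of 23 DNA repair and damage signalling genes, 12 were at least 2-fold lower and none higher, with medians of -1.16 and -1.11 (random ranges -0.34 to 0.20 and -0.29 to 0.19). Among them were RAD51AP1 (-2.87 and -2.34), the helicase BLM (-2.11 and -2.35), FANCI (-2.50 and -1.87) and the exonuclease EXO1 (-2.37 and -1.97). Together, the 3 proliferation lists held 121 tested genes, of which 97 were at least 2-fold lower with both siRNAs. The other 301 genes that were lower with both lay outside them. The lists do not hold every cell division gene: SPC25 and KIFC1, named above, are among the 301.

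Among 21 cyclin-dependent kinase inhibitors and RB pathway genes, 1 was at least 2-fold higher and 2 were lower with both siRNAs, and the medians of -0.07 and -0.06 lay inside the random ranges, with both turning positive among genes above the 75th percentile of signal (0.16 and 0.29). The higher gene was CDKN2A, which encodes p16 and ARF, with a signal of 432.5 in the control, 1040.0 with SETD8 siRNA 1 and 1114.8 with SETD8 siRNA 2 (1.27 and 1.37), but it was under 2-fold with both when probe sets were averaged (0.83 and 0.79). The lower genes were E2F8 (-3.13 and -2.87) and RBL1 (-3.05 and -1.93, or -1.55 with either siRNA when probe sets were averaged). CDKN2B, which encodes p15, was 9.93-fold higher with SETD8 siRNA 1 and 1.66-fold higher with SETD8 siRNA 2, and the latter value became -0.16 on the log2 scale when probe sets were averaged. CDKN1A, which encodes p21, had 1.38 and 0.44, CDKN1B -0.85 and -1.33, and CCND1 0.27 and 0.90. The cyclin D2 gene CCND2 had 0.86 with SETD8 siRNA 1 and 3.69 with SETD8 siRNA 2 (2.69 with probe sets averaged). RB1 had -0.25 with both, a sign that turned when its probe sets were averaged. Of 32 p53 targets, 2 were at least 2-fold higher with both siRNAs, PLK3 (1.83 and 1.09, or 0.40 and 0.37 with probe sets averaged) and SERTAD1 (1.48 and 1.38). The medians of the p53 targets were 0.42 and 0.20, above random ranges of -0.16 to 0.17 and -0.14 to 0.18.

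The H4K20 and chromatin methylation list had 36 tested genes, among them some that are not methylation enzymes, such as LMNB1 and HMGA2. Of the 36 genes, 3 were at least 2-fold lower with both siRNAs and none higher. These were LMNB1, with a signal of 4162.8 in the control against 450.2 and 410.5, the H3K27 methyltransferase EZH2 (-1.81 and -2.17) and the H3K36 methyltransferase NSD2 (-1.81 and -1.89, or -0.51 for SETD8 siRNA 2 without shared probe sets). The list medians were -0.29 and -0.40, under random ranges of -0.22 to 0.16 and -0.18 to 0.17, and 23 members were lower with both at any size. KMT5B and KMT5C encode the enzymes that add further methyl groups to H4K20. KMT5B had 0.11 and -0.11, a sign that turned for SETD8 siRNA 1 without shared probe sets (-0.42), and KMT5C, a dim gene with a control signal of 92.0, had -0.48 and -2.51, the latter being -1.75 with the pseudocount. HMGA2 had 0.57 and 0.56, or 0.04 and -0.51 without shared probe sets, so neither increase held there.

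Histone genes that passed the filter were higher as a set. Of 20 members of the replication-dependent histone list that passed the filter, 4 were at least 2-fold higher with both siRNAs and none was lower with both: H2BC11, H4C8 (1.82 and 2.04), H2BC4 (1.25 and 1.61) and H2BC5 (1.18 and 1.30). Their list medians were 0.75 (SD over members 0.87) and 0.99 (SD 1.19), above random ranges of -0.33 to 0.25 and -0.29 to 0.24. Without the filter on low signal, 35 members gave 0.14 and 0.38. Histone genes are near-identical, and the signal of a single one is uncertain where probe sets bind several.

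Secretory genes differed between the siRNAs. Of 41 senescence-associated secretory factors, 25 were at least 2-fold higher and 1 lower with SETD8 siRNA 1, 7 were higher and 6 lower with SETD8 siRNA 2, and 5 were higher with both: NRG1 (2.34 and 2.22), CXCL8 (4.12 and 1.23, the former 5.26 with probe sets averaged), EREG (4.30 and 1.29), STC1 (2.77 and 1.20) and PLAT (1.71 and 1.09). The list median was 1.71 (SD over members 2.74) with SETD8 siRNA 1, above the random range of -0.12 to 0.15, and 0.10 (SD 0.95) with SETD8 siRNA 2, inside its range of -0.09 to 0.18. The median difference, siRNA 2 minus siRNA 1, was -1.57 against a random range of -0.14 to 0.15. IL6, the interleukin, had a signal of 752.6 in the control, 14925.4 with SETD8 siRNA 1 and 1193.0 with SETD8 siRNA 2, and CXCL1, a neutrophil chemokine, had 186.5, 24635.4 and 241.1. Among genes above the 75th percentile of signal the median difference was -0.86.

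Interferon-response genes were higher with both siRNAs, more so with SETD8 siRNA 1. Of 37 genes, 6 were at least 2-fold higher with both and none lower: MX1, IFI27 (3.79 and 2.29), BST2 (at least 4.11 and 1.58, its control signal being at the floor, and the former 3.27 with the pseudocount), CXCL11 (3.52 and 1.31), IFI6 (2.70 and 1.71) and ISG15 (1.76 and 1.20). Without shared probe sets CXCL11 had 2.24 and 0.64, under 2-fold with SETD8 siRNA 2, where it also lay just under 2-fold with the pseudocount or with probe sets averaged. The medians were 1.06 and 0.38, above random ranges of -0.24 to 0.16 and -0.21 to 0.17, and the median difference between the siRNAs was -0.99. Of 25 immediate early and MAP kinase feedback genes, 4 were higher with both siRNAs and none lower with both: the phosphatase DUSP4 (4.90 and 2.29, or 3.99 and 1.72 with probe sets averaged), the transcription factor EGR3 (4.86 and 2.24), and the feedback inhibitors SPRY4 (2.06 and 1.54) and SPRY2 (1.39 and 1.01). With SETD8 siRNA 1, 11 of the 25 were at least 2-fold higher and 4 lower, and with SETD8 siRNA 2, 8 were higher and 0 lower. The medians were 0.83 and 0.54, outside random ranges of -0.20 to 0.21 and -0.18 to 0.20, and the first was 0.25 above the 75th percentile of signal. Of 30 lysosome and autophagy genes, 24 were higher with both siRNAs at any size and 1 lower, with medians of 0.48 and 0.39 (random ranges -0.15 to 0.19 and -0.13 to 0.19). FUCA1, a lysosomal fucosidase (1.30 and 1.38), and the cholesterol transporter NPC1 (1.45 and 1.05) were at least 2-fold higher with both, but both genes were under 2-fold with both siRNAs when probe sets were averaged.

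**Figure D3:**
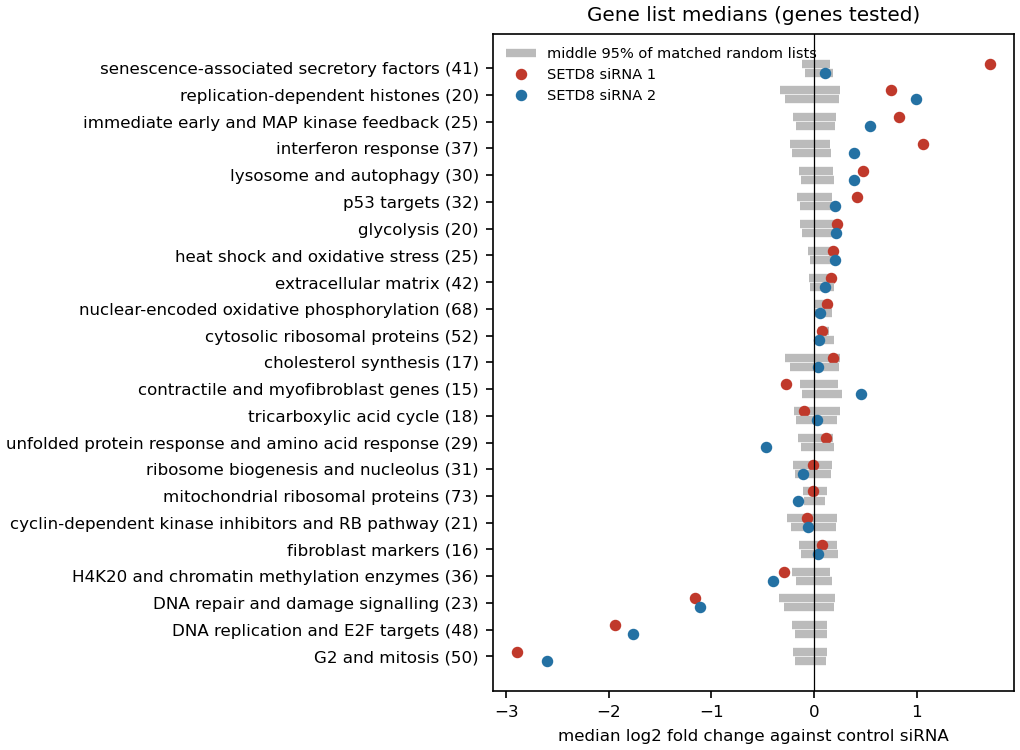
Median log2 fold change (horizontal axis) of each gene list with at least 10 tested genes (number in brackets), red for SETD8 siRNA 1 and blue for SETD8 siRNA 2, with grey bars for the middle 95% of 10000 random lists matched on signal. G2 and mitosis genes are lowest (-2.89 and -2.60), and secretory factors are highest with SETD8 siRNA 1 (1.71) but inside the grey bar with SETD8 siRNA 2 (0.10).

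Ribosomal and mitochondrial gene lists had medians near 0. No gene among 52 cytosolic ribosomal proteins reached 2-fold, and the list medians were 0.08, inside the random range, and 0.04, just under its range of 0.05 to 0.19, or -0.02 and -0.09 after quantile normalization. The median of the mean over both siRNAs was 0.059, at percentile 3.60 of the random lists, and it was -0.052 after quantile normalization, so its direction is not settled. For 31 ribosome biogenesis and nucleolus genes the medians of -0.01 (0.02 with median scaling) and -0.11 lay inside the random ranges, and no gene was at least 2-fold apart from the control with both siRNAs. In that list the rRNA methyltransferase FBL had -0.71 and -1.12, UTP20 -0.91 and -0.80, and nucleolin, NCL, -0.15 and -0.21. The 73 mitochondrial ribosomal proteins had medians of -0.01 (0.02 with median scaling) and -0.16, the latter under the random range of -0.09 to 0.11, with MRPL11 at -0.52 and -0.74 and MRPL36 at 0.73 and 0.50. The 68 nuclear-encoded oxidative phosphorylation genes (0.13 and 0.06) and 18 tricarboxylic acid cycle genes (-0.10 and 0.03) had medians inside the random ranges, and after quantile normalization the values for SETD8 siRNA 2 turned to -0.02 and -0.01. No member of either list was at least 2-fold apart from the control with both siRNAs. Of 20 glycolysis genes, 1 was higher with both siRNAs, the hexokinase HK2 (2.15 and 1.61, or 0.76 for SETD8 siRNA 1 with probe sets averaged), and the medians were 0.22, just above the random range of -0.14 to 0.20, and 0.21, inside its range. MYC had -0.32 and 0.11.

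Among 42 extracellular matrix genes, 1 was lower with both siRNAs, the basement membrane collagen COL15A1, with a signal of 4303.9 in the control, 966.4 with SETD8 siRNA 1 and 1073.5 with SETD8 siRNA 2, and the medians were 0.16, just above the random range of -0.05 to 0.15, and 0.10, inside. The 29 unfolded protein and amino acid response genes had medians of 0.12, inside the random range, and -0.47, under the range of -0.13 to 0.20. Of these, DNAJB9 was higher with both (1.28 and 1.07, the latter just under 2-fold with probe sets averaged) and the cystine transporter SLC7A11 lower (signals of 8674.3, 4332.1 and 3718.5), while PHGDH of serine synthesis had -0.82 and -1.91. The 25 heat shock and oxidative stress genes (0.18 and 0.20) and 17 cholesterol synthesis genes (0.18 and 0.03) had medians inside the random ranges. Both cholesterol medians were below 0 with probe sets averaged (-0.09 and -0.11), and the heat shock median for SETD8 siRNA 1 was -0.05 without shared probe sets. The 15 contractile and myofibroblast genes differed in sign, with medians of -0.27 and 0.46, both outside the random ranges of -0.14 to 0.23 and -0.12 to 0.27.

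Markers of the cell types the culture could hold were read as levels. The median signal of 17 fibroblast markers was 3873 in the control, 3480.9 with SETD8 siRNA 1 and 3965.8 with SETD8 siRNA 2, and 16 passed the filter. Epithelial markers had medians of 37.6, 27.3 and 23.7 (4 of 12 above the filter), endothelial markers 16.1, 24.9 and 22.7 (3 of 8), and leukocyte markers 18.4, 12.7 and 18.7 (0 of 7). Of the epithelial and endothelial markers, KRT18 reached 2987.4, 2962.8 and 6010.1, and TEK 1251.3, 1274.8 and 2033.1. As changes, the 3 endothelial markers above the filter had medians of 1.13, above the random range of -0.93 to 0.87, and 0.44, inside its range. The 4 epithelial markers had -0.12, inside, and 0.657, just above the range of -0.712 to 0.651. Lists this short rest on few genes. The per-siRNA medians of the fibroblast marker changes were 0.07 and 0.04 (0.01 and -0.05 after quantile normalization), whereas the median of the mean over both siRNAs was -0.13, under its random range of -0.10 to 0.20.

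Between the 2 SETD8 siRNA arrays, 1546 genes were at least 2-fold apart, 761 higher and 785 lower with SETD8 siRNA 2. The genes most in excess with SETD8 siRNA 1 were CXCL2, CCL20 and IL1B, which encode inflammatory factors. An inflammatory theme among the other genes in excess was not tested. The chemokine CXCL2 had a signal of 22.8 in the control, 7577.2 with SETD8 siRNA 1 and 17.8 with SETD8 siRNA 2, and interleukin 1 beta, IL1B, had 269.4, 20515.4 and 57.6. The chemokine CCL20 was at the floor in the control and with SETD8 siRNA 2 and was at least 389.8-fold higher with SETD8 siRNA 1. With the pseudocount its log2 fold change with SETD8 siRNA 1 was 8.05, below that bound. The genes most in excess with SETD8 siRNA 2 were the chemokine CXCL12 (546.7, 16.2 and 1478.8), TMEM178B (56.3, 27.3 and 2192.8) and PNMA2 (30.2, 9.9 and 481.1). With 1 array each, a difference between the siRNAs cannot be separated from one between cultures or arrays.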

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

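The tests of explanations in this part were chosen after the results were seen. The contractile and myofibroblast genes stood out because their medians had opposite signs with the 2 siRNAs, with a median difference, siRNA 2 minus siRNA 1, of 0.62 (random range -0.19 to 0.21). Examples are TAGLN (-1.06 and 0.63), CNN1 (-1.17 and 1.24) and LMOD1 (-0.80 and 1.56). A count of 82 genes was at least 2-fold changed in opposite directions, 39 higher with SETD8 siRNA 1 and lower with SETD8 siRNA 2 and 43 the reverse, against 41.3 ± 6.51 (SD over 100 simulations) for unchanged arrays with the wider noise and 2.44 ± 1.28 with the narrower. The contractile list was flagged because its medians lay outside the random ranges with opposite signs, so its difference is no separate support. Its random range comes from genes of the same arrays, not from unchanged arrays. The count of 82 exceeded both simulated values, whose noise was taken from the same difference between the siRNAs. Neither result was tested against replicate error, which needs more than 1 array per siRNA. Among 2986 unnamed probe sets above the filter, which enter no comparison of genes, 49 were at least 2-fold higher and 54 lower with both SETD8 siRNAs, where each SETD8 siRNA array in the place of the control gave 84 and 68 (siRNA 1) and 44 and 62 (siRNA 2).

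Proliferation genes were lower with both SETD8 siRNAs. The choice among the scalings tried does not account for it, since the G2 and mitosis median nearest to 0 under median or quantile scaling was -2.72. The arrays already had similar medians, so these scalings could move values little, and neither would reveal a shift of all genes. A control culture or array that stood apart, for example one that was sparser when harvested, cannot be told apart from an effect of SETD8 knockdown, because there was 1 control array. The SETD8 siRNA arrays differed by a median of 0.21 for this list, which a faulty control would also give. A lower rate of division after SETD8 knockdown therefore stays a hypothesis.

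Secretory factors were higher with SETD8 siRNA 1 than with SETD8 siRNA 2. For a common factor of response size, the G2 and mitosis list gave a ratio of 1.11 between the siRNAs. That ratio predicts a secretory median of 0.11 with SETD8 siRNA 1, where 1.71 was observed. The secretory median with SETD8 siRNA 2 was 0.10, inside its random range, so any ratio near 1 would miss 1.71. This comparison therefore restates the pattern and adds no separate evidence. The choice of scaling does not account for the pattern, with the limit on scaling given above, since the difference nearest to 0 under the other scalings was -1.56. An effect of the siRNA 1 sequence or its delivery other than through SETD8 stays open, with the interferon list also differing by -0.99, because each sequence had 1 array. Stronger knockdown by siRNA 1 with a response that sets in past a threshold also stays open and was not tested, and KMT5A had -0.48 and -0.44, and -0.42 and -0.21, on its 2 probe sets that are not shared.

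Histone genes that passed the filter were higher as a set with both SETD8 siRNAs. Probe sets shared between histone genes are argued against as the whole cause for the mean over both siRNAs, since 13 members without them had a median of 0.58 (random range -0.37 to 0.28). The filter uses the mean of all 3 arrays, so a rise can carry a gene over it, and with no filter 35 members had a median of only 0.33 (random range -0.21 to 0.19). Noise of dim probe sets was examined with a cut on the control array alone. With shared probe sets kept, 7 members above its 75th percentile had a median of 0.89 (random range -0.48 to 0.26). Near-identical histone genes with shared probe sets may not give independent values, whereas the random lists hold separate genes, so this range may be too narrow. Shared probe sets were not left out at that cut, so it does not decide the question. At the median of the control array 20 members had 0.70, and 13 without shared probe sets had 0.58 (0.16 and 0.79 by siRNA). The 0.16 was not set against random lists, so a rise with SETD8 siRNA 1 without shared probe sets is not shown. More polyadenylated histone transcripts in cells that left the cycle may be a candidate explanation, but tails were not measured, and SLBP, the histone stem-loop binding protein, had a mean change of -0.30 (-0.42 and -0.18), which decides nothing. Of the 20 members 14 were higher and 2 lower with both siRNAs at any size, and H3C8 (1.00 and -2.59) was the only one at least 2-fold lower with SETD8 siRNA 2.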

How the results depend on the processing

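No paired analysis was possible because each siRNA had 1 array, and for the same reason no array could be left out. Direction over both siRNAs changed in some setting for the medians of the cytosolic ribosomal, extracellular matrix (0.10 to -0.01 after quantile normalization), cholesterol, epithelial marker and cyclin-dependent kinase inhibitor lists, all near 0 in the main setting. Counts of genes higher with both, lower with both and apart between the siRNAs (185, 398 and 1546) were 460, 737 and 3310 with no filter, 80, 204 and 675 above the 75th percentile, 565, 907 and 3423 at 1.5-fold, and 57, 191 and 621 at 3-fold, as the number of genes tested or the threshold sets them. The other settings gave 126 to 207 higher and 289 to 366 lower genes. Of the 185 and 398, 185 and 353 remained after quantile normalization, and 104 and 299 with probe sets averaged. At the 2-fold threshold the share of higher genes ran from 27.8% to 38.4% over the settings (31.7% in the main one). The correlation of 0.449 was 0.492 above the 75th percentile, 0.477 with probe sets averaged and 0.404 without the proliferation lists, the last chosen after seeing the data. KMT5A (-1.12 and -0.68) was -0.64 and -0.39 with probe sets averaged and -0.48 and -0.44 without shared ones. The ribosomal median of 0.059 was 0.094 with median scaling, -0.052 after quantile normalization, 0.025 with probe sets averaged and 0.031 without shared ones. The replication median over both siRNAs (-1.79) was -1.71 with the pseudocount, and G2 and mitosis (-2.76) was -2.86 without shared probe sets. The secretory median over both (0.99) was 1.09 with the pseudocount, 0.69 above the 75th percentile, 0.90 with probe sets averaged and 0.70 without shared ones. For these values the cause was not tested. Of all list medians under the alternatives, 136 moved by less than 1 SD of the random lists and 35 by more. Of the named genes' values, 1587 moved by less than the typical spread of 1 array and 107 by more. The sides of the random range changed in some settings for the ribosomal, fibroblast, glycolysis, mitochondrial ribosomal and unfolded protein lists. Signal over background limits the dim genes: 647 of 3077 genes in the lowest signal quartile were 2-fold apart between the SETD8 siRNA arrays, against 206 of 3077 in the highest.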

Other observations

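Families of genes sharing a symbol stem were grouped after the data were seen, and 19 of 256 families lay under and 18 above the middle 95% of random lists, where 12.8 in all would by chance. Nucleoporins, the proteins of the nuclear pore, were lower: 19 of 21 with both siRNAs at any size and 1 higher, with medians of -0.66 and -0.55 (random range of the mean over both -0.22 to 0.17). NUP155 had -1.12 and -1.32, and NUP107 -0.96 and -0.89. All 7 measured subunits of the augmin complex (HAUS), which acts in spindle microtubule nucleation, were lower, with medians of -0.91 and -0.73, and HAUS6 had a signal of 1801.9 in the control, 898.4 with SETD8 siRNA 1 and 879.0 with SETD8 siRNA 2. The 10 subunits of the RNA exosome (EXOSC) had medians of -0.34 and -0.42, with EXOSC8 at -1.22 and -1.56, and 7 importins (IPO) had -0.54 and -0.45. Above the range lay 29 collagen genes (COL), with medians of 0.53 and 0.11. So did 9 CXCL genes (6.41 and 0.13) and 14 MMP genes (0.94 and -0.10). The range is that of the mean over both siRNAs, so SETD8 siRNA 1 can carry a family above it. Of the MMP genes, 6 were at least 2-fold higher with SETD8 siRNA 1 and 0 with SETD8 siRNA 2. Members of both families are in the secretory list, CXCL10 and CXCL11 are in the interferon list, and collagens are in the extracellular matrix list. These 3 families are thus no separate support for those results. The medians of all families named here kept their signs under median and quantile scaling.

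Several other genes differed widely between the siRNAs. Of those below, POSTN belongs to the extracellular matrix list and ID1 and ID3 to the immediate early list, and the rest lie outside the lists. PTGS2, the inducible cyclooxygenase, had 7.63 with SETD8 siRNA 1 and 0.64 with SETD8 siRNA 2, and the cartilage collagen COL10A1 had 5.79 and -0.25, with 1 of its 2 probe sets above the filter showing these signs. POSTN, the matrix protein periostin, had 1.13 and -4.76. With SETD8 siRNA 2, ANKRD1 (0.39 and 4.97) and the BMP-responsive genes ID1 (0.10 and 2.58) and ID3 (0.25 and 1.89) were higher. Of 9 pregnancy-specific glycoprotein genes (PSG), 6 were at least 2-fold lower with SETD8 siRNA 1 and at least 2-fold higher with SETD8 siRNA 2, with medians of -1.06 and 1.32. These genes are near-identical, so their probe sets are not independent, and the signs held under both other scalings. No explanation of these values was tested.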
